A study of Mus musculus with 13 samples.

How the data were processed

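Total RNA from snap-frozen material of BNL-MEA tumour-bearing Balb/c mice had been prepared with the AllPrep kit and sequenced from TruSeq stranded mRNA libraries. The processing notes of the authors name cutadapt 2.4, STAR 2.7.2a and genome build GRCm38. The counting program, the annotation release, the strand setting and any filters are not stated. The deposited tables, 1 for each batch, hold counts, that is raw read counts per Ensembl gene for each library, with no normalization. Their values were checked to be whole numbers from 0 with column sums that differ. Both tables list the same 54446 Ensembl identifiers. A symbol from the reference annotation (GENCODE M21) was found for 54409 of them and not for 37. Library totals ran from 20668524 to 26366606 counts.

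Of the columns of the p103 table, 4 carry accessions of samples outside the sample list of this series and were not used here. The descriptions of the vehicle p103 samples cite these accessions. Leaving them out follows a rule on column names and not their values, but it was applied after comparisons with them had been fitted. Without them anti-PD1 has no vehicle group here. The planned comparisons of anti-PD1 with vehicle in p103, of the effects of the treatments and of the vehicle groups are therefore not reported, nor is the correlation of effects. The remaining 9 libraries were grouped by treatment and batch into vehicle p106, ironized anti-PD1 p106 and anti-PD1 p103 (n = 3 each). There was 1 comparison, ironized anti-PD1 against vehicle in p106. No gene or list was tested between anti-PD1 and the p106 groups, because treatment and batch differ together. Shares of counts of the anti-PD1 libraries were set beside those of the vehicle p106 libraries, by intervals that cover counting error only.

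Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3 and scaled by TMM. The comparison was tested on its 6 libraries with edgeR's quasi-likelihood test (robust, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. SE values of log2 changes are the absolute log2 change divided by the square root of the quasi-likelihood F statistic. CPM values of the comparison use TMM-scaled library sizes. CPM ranges over all libraries, CPM of the anti-PD1 group and list scores use the unscaled library totals. The common biological coefficient of variation was 36.8%. With 3 against 3 libraries the smallest two-sided exact p of a single measure is 0.1, so no permutation tests of single measures were made.

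A set of 51 gene lists for cell types, pathways and other tissues was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1, two-sided, preset correlation between genes of 0.01) with Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, and fry was run as well. All other list tests, also those with a library left out, kept the preset correlation. List members were also adjusted over the list alone. Counts of members are of those tested, since members below the count filter were left out. List scores are the mean log2 CPM of the members in a library. The share of counts of a list in a library has a 95% Wilson interval.

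The named genes were a panel of 14 genes of the checkpoint, T cells, iron handling and liver (Pdcd1, Cd274, Cd8a, Cd3e, Gzmb, Ifng, Foxp3, Fth1, Ftl1, Tfrc, Slc40a1, Hmox1, Alb and Afp). To these were added the 8 largest changes in each direction with an adjusted p under 0.05, a mean log2 CPM of at least 1, no overlap of CPM between the groups and a symbol that is not a predicted, RIKEN or pseudogene model. Where fewer than 4 genes passed in a direction, the 4 with the smallest unadjusted p under the same other conditions were named and said not to have passed. For each list called, the 3 members with the smallest unadjusted p in the direction of the list were chosen, and for 2 lists only 2 of the 3 are given in the text. Coordinates are those of GENCODE M21 on GRCm38.

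The alternatives were RLE scaling, upper quartile scaling and library size alone, no filter, a strict filter (CPM of at least 1 in every library of a group), DESeq2 1.42.0, limma voom with quality weights, glmTreat with a 1.5-fold threshold, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were the hepatocyte score as a covariate and leaving out the most hepatocyte-rich library of each group.

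The gene and list tests were tested on simulated data with the group sizes, depths and dispersions of the comparison. Of 100 genes set to a 2-fold change edgeR called 37 and DESeq2 54, and of 100 set to a 4-fold change 75 and 86. All these genes and the changed list were set in the same simulated data, in which edgeR made 6 false calls and DESeq2 65. Camera called the 1 list set to a 1.5-fold change and 0 of 46 others. The simulated genes were drawn independently of each other. Every other split of the 6 libraries into groups of 3 was fitted in the same way.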

Results

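Gene expression was measured by RNA sequencing in 9 libraries from Balb/c mice bearing BNL-MEA tumours, a mouse hepatocellular carcinoma line. Batch p106 held 3 vehicle libraries and 3 libraries from mice given ironized anti-PD1, whose preparation the labels do not describe. Anti-PD1 is an antibody against the T cell checkpoint receptor PD-1. Batch p103 added 3 libraries from mice given anti-PD1. The vehicle libraries of p103 were not used here, so the anti-PD1 group is reported as values without a comparison. The labels also do not state the site of the tumours, the dose or the time of sampling. Library totals ran from 20668524 to 26366606 counts.

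Albumin (Alb), the main secreted protein of hepatocytes, ranged from 2.76 to 4174 CPM (counts scaled to the library total) between libraries. The 26 hepatocyte genes fixed for this purpose took from 0.0101% (95% Wilson interval 0.00972 to 0.0106) of counts in anti-PD1 replicate 2 to 1.18% (1.18 to 1.18) in ironized anti-PD1 replicate 1. Within groups the highest and lowest hepatocyte shares differed 23.9-fold for vehicle p106, 49.5-fold for ironized anti-PD1 and 112-fold for anti-PD1. Genes of exocrine pancreas and gut took 3.09% (3.08 to 3.10) of counts in anti-PD1 replicate 2 and 0.256% (0.254 to 0.258) in anti-PD1 replicate 3. Their share was at most 0.00130% (0.00116 to 0.00145) in the other libraries. Skeletal muscle genes took 0.111% (0.110 to 0.113) of counts in ironized anti-PD1 replicate 3 and at most 0.0181% (0.0176 to 0.0187) elsewhere. B and plasma cell genes took 0.0766% (0.0754 to 0.0778) in anti-PD1 replicate 2. Reads carried no molecular identifiers, so these intervals cover counting error only.

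**Figure D1:**
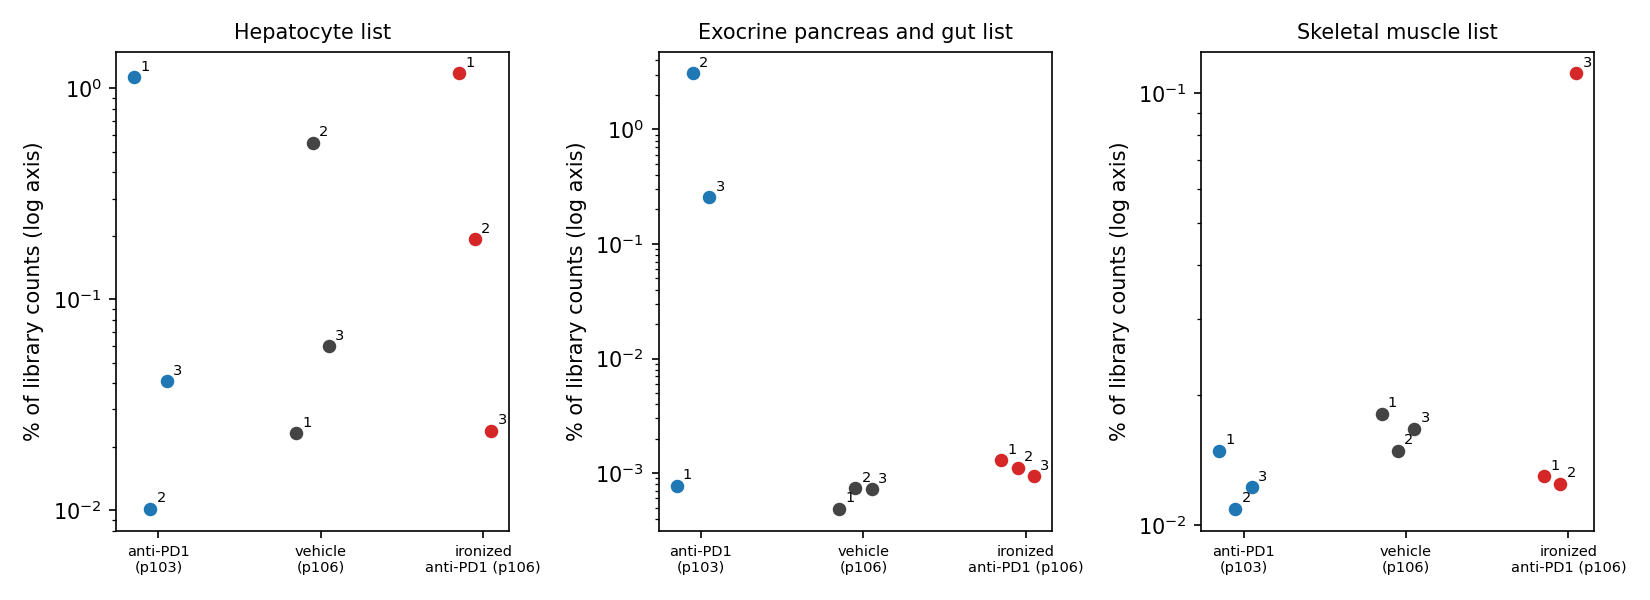
Percent of all counts (log axis) in each of the 9 libraries taken by hepatocyte, exocrine pancreas and gut, and skeletal muscle genes, with points numbered by replicate. Hepatocyte genes ranged from 0.0101% to 1.18%, and pancreas and gut genes reached 3.09% in anti-PD1 replicate 2.

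The comparison asked which transcripts differed between ironized anti-PD1 and vehicle in batch p106. Genes of the type I interferon response fell as a group. All 22 members had negative log2 changes, with a median of -1.21 (camera adjusted p = 2.08e-34, adjusted p = 0.373 with an estimated correlation), and 16 were lower when adjusted over the list alone. When adjusted over all genes 0 members were called. The estimated correlation between members was 0.787, so they are not separate pieces of evidence. The ubiquitin-like antiviral protein gene Isg15 (ENSMUSG00000035692.6, GRCm38 chromosome 4, 156199424 to 156200818) was at 21.7 ± 5.05 CPM (SD, n = 3) with vehicle and 7.48 ± 1.40 CPM (n = 3) with ironized anti-PD1, a log2 change of -1.54 (SE 0.23). The antiviral genes Ifit1, at 14.4 ± 6.65 and 2.93 ± 0.582 CPM, and Rsad2 had log2 changes of -2.30 (SE 0.38) and -1.68 (SE 0.31). The list was called in 6 of 6 fits with a library left out, with medians from -1.51 (without vehicle replicate 3) to -0.80 (without vehicle replicate 1).

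MHC class II presentation genes rose as a group. All 11 members had positive log2 changes, with a median of 1.53 (camera adjusted p = 5.19e-17, adjusted p = 0.373 with an estimated correlation), and 6 were higher when adjusted over the list alone. When adjusted over all genes 0 members were called. The class II beta chain H2-Eb1 (ENSMUSG00000060586.10, chromosome 17, 34305867 to 34316674) was at 14.7 ± 3.88 CPM (n = 3) with vehicle and 78.4 ± 45.5 CPM (n = 3) with ironized anti-PD1, a log2 change of 2.41 (SE 0.48). The alpha chain H2-Aa was at 22.6 ± 3.58 and 116 ± 71.3 CPM, a log2 change of 2.37 (SE 0.49). Ciita, the transactivator of class II genes, had a log2 change of 2.37 (SE 0.52). This list was also called in 6 of 6 fits with a library left out, with medians from 1.20 to 1.90. Those fits again used the preset correlation, where 0.618 was estimated. The mean log2 CPM of the class II list in ironized replicates 1 to 3 was 3.98, 4.36 and 5.08, and that of cytotoxic lymphocyte genes was -1.28, -0.37 and 0.16. T cell genes, at -0.70, -0.006 and -0.19, did not keep this order. Hepatocyte genes, at 6.93, 4.36 and 0.94, ran the other way, and muscle genes, at -1.34, -1.44 and 4.61, were highest in replicate 3. These lists were set side by side after their values were seen.

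The mean log2 CPM of the interferon genes was 4.05 ± 0.67 (SD, n = 3) with vehicle p106 and 2.94 ± 0.11 (n = 3) with ironized anti-PD1. For MHC class II genes the means were 3.31 ± 0.26 with vehicle p106 and 4.47 ± 0.56 with ironized anti-PD1. Neither score overlapped between these groups of 3, which chance gives for 10% of measures chosen beforehand. These 2 lists are shown because their p values were the smallest, so that share does not hold for them. Scores of some lists that were not called did not overlap either. T cell checkpoints and exhaustion ran from 0.807 to 0.947 with vehicle p106 and from 1.16 to 1.39 with ironized anti-PD1.

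**Figure D2:**
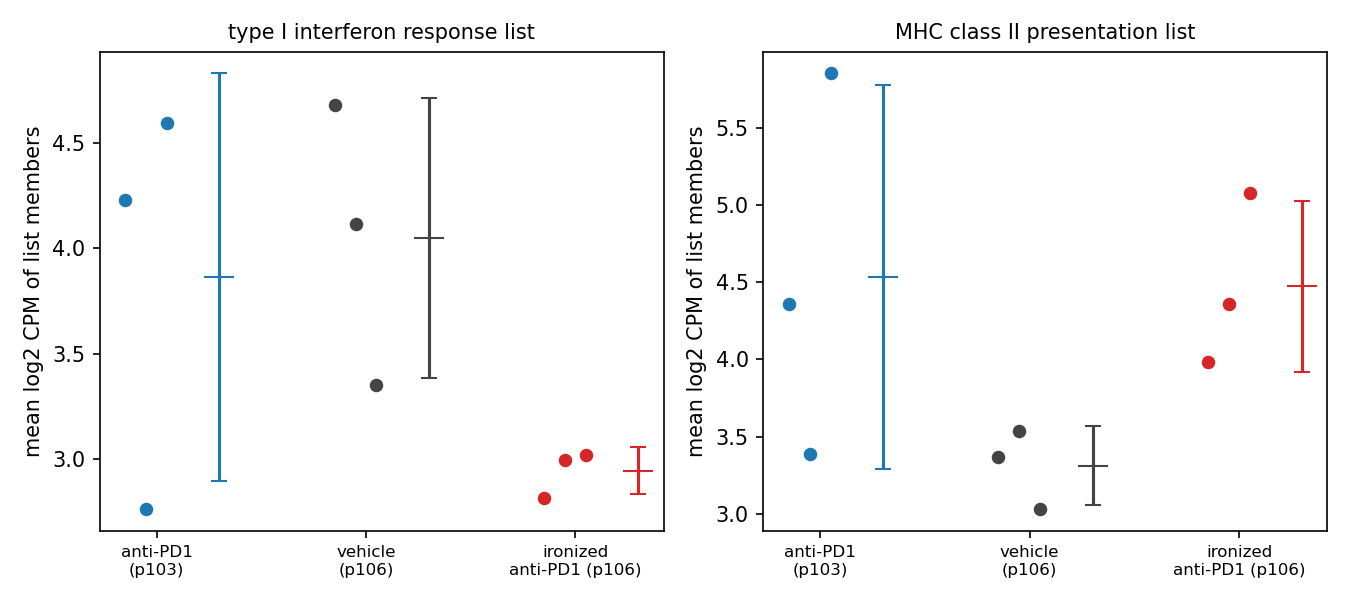
Mean log2 CPM of the type I interferon and MHC class II lists in each library (points), with group mean and SD (bars) for the 3 groups. With ironized anti-PD1 the interferon score was 2.94 ± 0.11 against 4.05 ± 0.67 in its vehicle group, and the MHC class II score 4.47 ± 0.56 against 3.31 ± 0.26.

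T cell genes rose as a group with ironized anti-PD1, with 14 of 14 members positive and a median of 0.68 (camera adjusted p = 1.67e-06, adjusted p = 0.495 with an estimated correlation). The T cell receptor kinase Zap70 and the surface proteins Cd3g and Cd6 had log2 changes of 1.52 (SE 0.41), 1.42 (SE 0.52) and 1.42 (SE 0.63), at levels of at most 1.46 CPM in either group. Cytotoxic lymphocyte genes were positive for 9 of 10 tested members, of 17 in the list (median 0.61, camera adjusted p = 0.00887, adjusted p = 0.650 with an estimated correlation), with the receptor Klrd1 at 1.19 (SE 0.44), the T cell co-receptor Cd8b1 at 1.21 (SE 0.50) and the protease Ctsw at 0.60 (SE 0.30). Macrophage genes were positive for 15 of 18 members (median 0.33, camera adjusted p = 0.00452, adjusted p = 0.604 with an estimated correlation), with Vsig4 at 1.36 (SE 0.72), Adgre1, which encodes F4/80, at 0.48 (SE 0.28) and the scavenger receptor Marco at 2.48 (SE 1.61). Without ironized replicate 1, the most hepatocyte-rich library of its group, Vsig4 was at 0.13 and Marco at 0.50, without vehicle replicate 2 Adgre1 was at 0.28, and without ironized replicate 2 Cd8b1 was at 0.71. The Kupffer cell gene Clec4f was also highest of the p106 libraries in ironized replicate 1, at 24.6 CPM. Without ironized replicate 3 the cytotoxic median was 0.24 (adjusted p = 0.676) and the macrophage median 0.04 (adjusted p = 0.434). The cytotoxic call was also lost without vehicle replicate 3 (0.56), and the macrophage call without vehicle replicate 2 (0.20). The highest cytotoxic median with 1 library left out was 1.08.

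Chemokine genes fell as a group, with 14 of 21 members negative (median -0.56, camera adjusted p = 0.00492, adjusted p = 0.373 with an estimated correlation). The interferon-inducible chemokine Cxcl10 was at 12.3 ± 8.65 CPM with vehicle and 3.78 ± 0.0351 CPM with ironized anti-PD1, a log2 change of -1.70 (SE 0.67). Its vehicle libraries were at 18.9, 15.5 and 2.53 CPM, so vehicle replicate 3 lay below every treated library. The monocyte chemoattractant Ccl7 and the neutrophil chemoattractant Cxcl2 had log2 changes of -1.53 (SE 0.55) and -2.84 (SE 1.02). Cxcl2 was at 2.04, 11.8 and 35.0 CPM in the vehicle libraries against 1.28 to 3.08 CPM, and its change was -1.61 without vehicle replicate 3. Without ironized replicate 1 the chemokine list was not called (-0.49, adjusted p = 0.133). Genes of classically activated macrophages had a median of -0.49 with 8 of 12 members negative (camera adjusted p = 0.00887, adjusted p = 0.374 with an estimated correlation), with the cytokines Tnf at -1.01 (SE 0.35) and Il6 at -0.81 (SE 0.37). Interferon-gamma response genes had a median of -0.30 with 15 of 21 negative (camera adjusted p = 0.00521, adjusted p = 0.650 with an estimated correlation), with the GTPases Igtp at -0.74 (SE 0.21), Irgm1 at -0.49 (SE 0.16) and Irgm2 at -0.82 (SE 0.29), of which Irgm1 was at -0.31 and Irgm2 at -0.54 without vehicle replicate 1. Ciita, the member with the smallest unadjusted p, moved against the list at 2.37 (SE 0.52). NF-kappaB targets had a median of -0.05 and a mean of -0.33 (camera adjusted p = 0.0423, adjusted p = 0.650 with an estimated correlation). The classically activated call was lost without vehicle replicate 2 (-0.45) or ironized replicate 1 (-0.30) or 3 (-0.53). With 1 library left out the median of that list ran from -0.89 to -0.23. The interferon-gamma call was lost without vehicle replicate 1 (-0.14) or 2 (-0.26) or ironized replicate 1 (-0.30), and the lowest median with 1 library left out was -0.49. The NF-kappaB call was lost without vehicle replicate 2 (0.04) or 3 (-0.09) or ironized replicate 1 (-0.02) or 3 (-0.13). The replicate number as a block also ended the classically activated call (-0.53) and the NF-kappaB call (-0.05). Without the most hepatocyte-rich library of each group none of these 4 lists was called, with medians of -0.24 for chemokines, -0.39 for classically activated macrophage genes, -0.26 for interferon-gamma and 0.05 for NF-kappaB targets.

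Nrf2 antioxidant targets were negative for 16 of 20 members (median -0.20, camera adjusted p = 0.00214, adjusted p = 0.650 with an estimated correlation). Heme oxygenase Hmox1, which frees iron from heme, was at 447 ± 366 CPM (n = 3) with vehicle and 133 ± 16.5 CPM (n = 3) with ironized anti-PD1, a log2 change of -1.75 (SE 0.62). The vehicle libraries were at 151, 333 and 856 CPM, so vehicle replicate 1 lay within the treated range (120 to 151 CPM), and without vehicle replicate 3 the change was -0.87. The glutathione synthesis gene Gclm and the sulfiredoxin gene Srxn1 had log2 changes of -0.49 (SE 0.17) and -0.37 (SE 0.14). The Nrf2 call was lost without vehicle replicate 3 (-0.10, adjusted p = 0.333) or ironized replicate 3 (-0.19), and the lowest median with 1 library left out was -0.32. Ferritin genes Fth1, at 2183 ± 607 and 1775 ± 222 CPM, and Ftl1 had log2 changes of -0.30 (SE 0.24) and -0.19 (SE 0.23). The transferrin receptor gene Tfrc had a log2 change of -0.13 (SE 0.25) and the iron exporter Slc40a1 was at 5.53 ± 4.13 and 15.5 ± 21.5 CPM. With 1 library left out the sign turned for Ftl1 (0.09 without vehicle replicate 3), Tfrc (0.09 without ironized replicate 3) and Slc40a1 (-0.80 without ironized replicate 1). Fth1 was at -0.12 without vehicle replicate 3 and -0.49 without vehicle replicate 1, Ftl1 at -0.33 without vehicle replicate 1 and Tfrc at -0.36 without ironized replicate 1. The list of 22 iron handling genes was not called (median 0.13, camera adjusted p = 0.543), nor were the 17 ferroptosis genes (median -0.05, camera adjusted p = 0.860).

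All 6 tested adipocyte genes, of 15 in the list, were positive (median 1.86, camera adjusted p = 3.87e-05, adjusted p = 0.374 with an estimated correlation), with the lipase Lpl at 1.64 (SE 0.50), Cidec at 3.50 (SE 1.38) and Car3 at 3.14 (SE 1.54). Fibroblast and collagen genes were positive for 15 of 21 members (median 0.18, camera adjusted p = 0.00377, adjusted p = 0.473 with an estimated correlation), with Fap at 1.08 (SE 0.31), the gelatinase Mmp2 at 0.87 (SE 0.28) and Col6a3 at 0.80 (SE 0.46). Their summed share of counts did not rise, at 1.67 ± 0.12% with vehicle and 1.67 ± 0.13% with ironized anti-PD1 (SD, n = 3 each). All 7 tested oncofetal liver genes, of 11 in the list, were positive (median 0.92, camera adjusted p = 0.00521, adjusted p = 0.373 with an estimated correlation), with Lin28b at 0.92 (SE 0.36), Peg3 at 1.96 (SE 0.96) and Gpc3 at 1.11 (SE 0.56). With the preset correlation these 3 lists were called in 6 of 6 fits with a library left out. The oncofetal call was lost without the most hepatocyte-rich library of each group (0.48, adjusted p = 0.0607). The adipocyte median was 0.66 without ironized replicate 3, 1.21 without ironized replicate 1 and 2.83 without vehicle replicate 2. The fibroblast median was 0.06 without ironized replicate 2 and 0.12 without ironized replicate 1, and the oncofetal median 0.60 without ironized replicate 1. Single genes moved as well: Lpl was at 0.91, Col6a3 at 0.39 and Peg3 at 0.60 without ironized replicate 1, Car3 at 0.66 without ironized replicate 3, Cidec at 6.80 without vehicle replicate 2 and Gpc3 at 1.86 without vehicle replicate 3.

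Hepatocyte genes were positive for 25 of 26 members (median 1.07, camera adjusted p = 0.00887, adjusted p = 0.825 with an estimated correlation), with the urea cycle enzyme Cps1 at 3.68 ± 3.70 and 14.8 ± 20.4 CPM, and with log2 changes of 1.78 (SE 1.62) for the cytochrome P450 gene Cyp3a11 and 1.53 (SE 1.66) for the amylase gene Amy1. Complement and acute phase genes had a median of 0.99 with 15 of 17 positive (camera adjusted p = 0.0385, adjusted p = 0.825 with an estimated correlation), with Saa3 at 1.41 (SE 1.30) and Saa2 at 2.16 (SE 2.15). Without ironized replicate 1 the changes of Cps1 (-0.27), Cyp3a11 (-0.60), Amy1 (-0.61) and Saa2 (-0.03) were negative, and that of Saa3 was 0.00407. Without vehicle replicate 2 the changes were 3.21 for Cps1, 3.16 for Cyp3a11, 4.18 for Amy1 and 4.27 for Saa2. The medians of the 2 lists without ironized replicate 1 were -0.94 and -0.55, and neither list was called without vehicle replicate 1 (0.51 and 0.48) or 3 (0.65 and 0.64). With the replicate number as a block they were -0.12 and 0.21 and neither was called, and the complement call was also lost with the strict filter. Cholangiocyte and hepatic progenitor genes had a median of 1.11 with 9 of 11 positive (camera adjusted p = 0.00233, adjusted p = 0.650 with an estimated correlation), with Sox9 at 1.01 (SE 0.50), Krt19 at 2.46 (SE 1.40) and Epcam at 0.462 ± 0.606 and 2.49 ± 2.18 CPM. That call was lost without ironized replicate 1 (0.59) or vehicle replicate 1 (0.95) and with the strict filter (0.65, 5 members). The highest median of this list with 1 library left out was 2.47. Krt19 was at 1.62 without ironized replicate 2, Epcam at 4.41 without vehicle replicate 2 and Sox9 at 0.66 without vehicle replicate 1. Erythroid genes had a median of 0.89 with 7 of 8 positive (camera adjusted p = 0.00337, adjusted p = 0.650 with an estimated correlation), with the heme synthesis gene Alas2 at 1.04 (SE 0.67) and the globin gene Hbb-bt at 0.89 (SE 0.61), and were not called without ironized replicate 2 (0.44) or vehicle replicate 1 (0.51) or 2 (0.72), nor without the most hepatocyte-rich library of each group (0.72). The highest erythroid median with 1 library left out was 1.65. Alas2 and Hbb-bt were at 0.65 and 0.48 without ironized replicate 2 and at 1.88 and 1.63 without vehicle replicate 3. Skeletal muscle genes had a median of 3.25 with 7 of 8 tested members positive, of 24 in the list (camera adjusted p = 0.00212, adjusted p = 0.650 with an estimated correlation), with the troponin gene Tnnt3 at 5.88 (SE 2.37), Actn3 at 3.59 (SE 1.52) and Ryr1 at 4.19 (SE 1.75). Without ironized replicate 3 the muscle median was 0.33 (adjusted p = 0.666), with Tnnt3 at 0.54, Actn3 at 0.26 and Ryr1 at 0.36.

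Lipid and cholesterol synthesis genes were positive for 22 of 26 members (median 0.17, camera adjusted p = 0.00501, adjusted p = 0.604 with an estimated correlation), with the transcription factor Srebf2 at 0.39 (SE 0.11), squalene synthase Fdft1 at 0.42 (SE 0.20) and the desaturase Scd2 at 0.26 (SE 0.15). Cell cycle genes were positive for 21 of 30 members (median 0.10, camera adjusted p = 0.00521, adjusted p = 0.667 with an estimated correlation), with the cyclin Ccnb2 at 0.58 (SE 0.09), Cenpe at 0.50 (SE 0.12) and Nusap1 at 0.37 (SE 0.09), and 1 member was higher when adjusted over the list alone. Heat shock protein genes were negative for 9 of 12 members (median -0.16, camera adjusted p = 0.00770, adjusted p = 0.374 with an estimated correlation), with Hsp90aa1 at -0.32 (SE 0.12), Hsph1 at -0.62 (SE 0.24) and Dnaja1 at -0.28 (SE 0.11). The lipid call was lost without vehicle replicate 1 (0.07), where Fdft1 was at 0.27 and Scd2 at 0.14. The cell cycle call was lost without vehicle replicate 3 (0.03) or ironized replicate 3 (0.08). The heat shock call was lost without vehicle replicate 2 (-0.13, with Hsph1 at -0.39) or ironized replicate 1 (-0.18), and without the most hepatocyte-rich library of each group (-0.13).

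**Figure D3:**
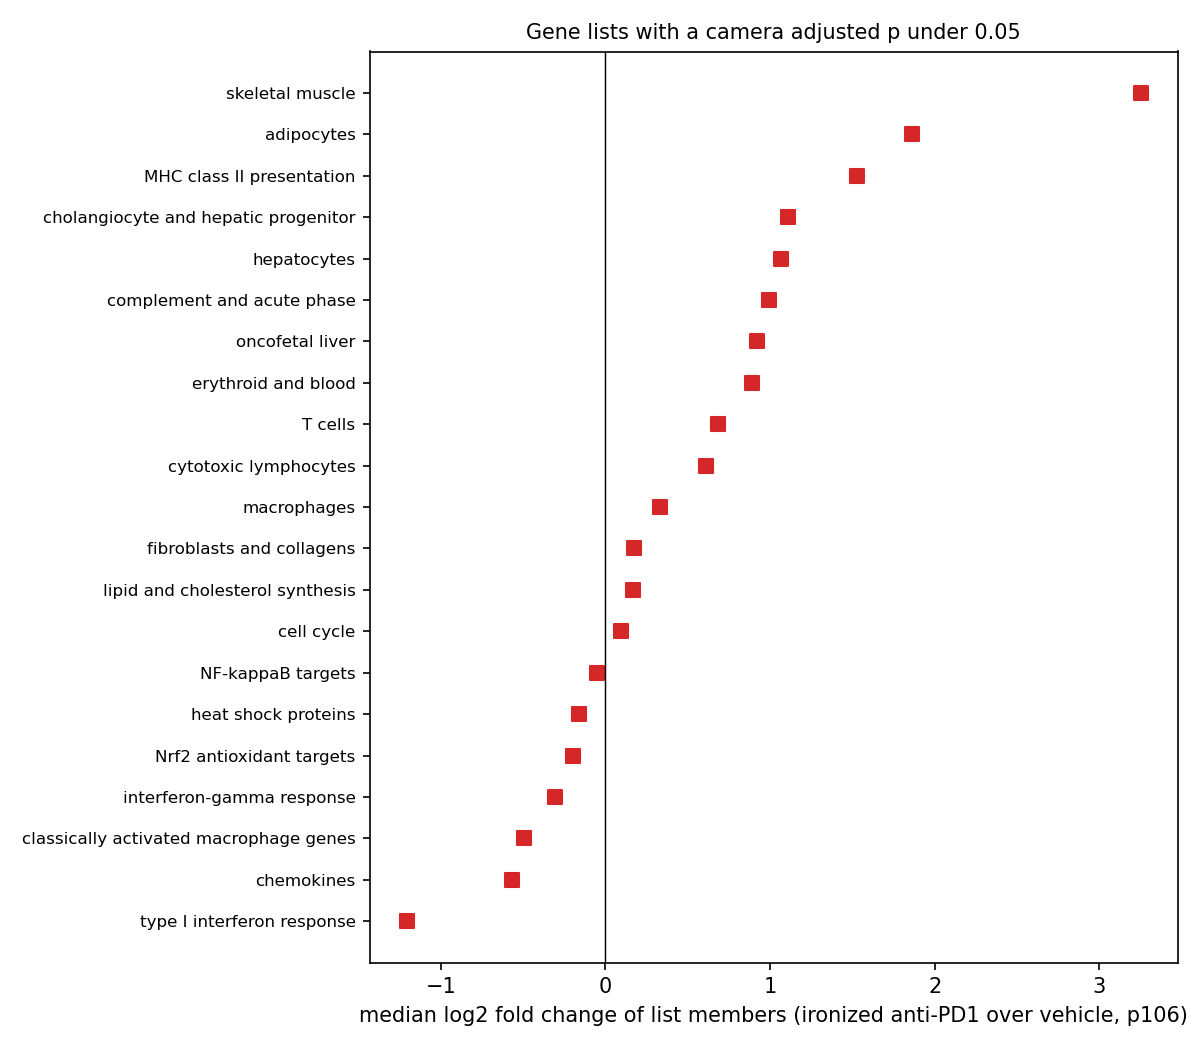
Median log2 change of each gene list called with ironized anti-PD1 against vehicle in batch p106. The type I interferon list was at -1.21 and the MHC class II list at 1.53.

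The single genes with the smallest p values for ironized anti-PD1 did not pass adjustment. The adhesion receptor gene Adgra1 (ENSMUSG00000025475.17, chromosome 7, 139834174 to 139878088) was at 1.02 ± 0.147 CPM (n = 3) with vehicle and 8.39 ± 2.45 CPM (n = 3) with ironized anti-PD1, a log2 change of 3.04 (SE 0.33). The collagen-binding proteoglycan Fmod was at 1.53 ± 0.185 and 6.29 ± 0.793 CPM, a log2 change of 2.04 (SE 0.25). Ace, which encodes angiotensin-converting enzyme, was at 14.5 ± 2.54 and 53.7 ± 18.9 CPM, a log2 change of 1.89 (SE 0.28). Tmem176a was at 60.3 ± 13.8 and 126 ± 1.90 CPM, a log2 change of 1.07 (SE 0.17). Gdf11, a TGF-beta family ligand, and the ubiquitin ligase Siah1b had log2 changes of -1.14 (SE 0.19) and -0.60 (SE 0.11). Pdcd1 was at 0.76 (SE 0.60), Cd274 at 0.21 (SE 0.41), Cd8a at 0.68 (SE 0.50), Cd3e at 0.59 (SE 0.58), Gzmb at 0.29 (SE 0.70) and Alb at 1.67 (SE 2.05). The CPM of the groups overlapped for each of these 6 genes. With 1 library left out the sign turned for Pdcd1 (-0.14 without ironized replicate 2), Cd274 (-0.03 without vehicle replicate 1), Gzmb (-0.71 without ironized replicate 3) and Alb (-0.49 without ironized replicate 1). Cd8a ran from 0.36 (without vehicle replicate 3) to 1.08 (without vehicle replicate 2) and Cd3e from 0.21 (without vehicle replicate 3) to 0.89 (without vehicle replicate 1). The highest values were 0.76 for Cd274 (without vehicle replicate 3), 0.72 for Gzmb (without ironized replicate 1) and 4.49 for Alb (without vehicle replicate 2).

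By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15128 genes passed for ironized anti-PD1 (smallest adjusted p = 0.654). An unadjusted p under 0.05 was found for 638 genes, 301 higher and 337 lower, where 5% of the genes is 756.4. At least 638 genes reached this in 6 of 10 splits of the libraries, counting the real one, with 1657 in the highest other split. DESeq2 called 50 genes, 25 in each direction, among them 6 of the 22 interferon genes, all lower, and 5 of the 11 MHC class II genes, all higher. Limma voom called 0, and DESeq2 made 65 false calls in simulated data of this design. Those data also held genes set to change, so 65 is no baseline for the 50 calls. Camera called 21 of 47 lists, 14 higher and 7 lower, and none of them with an estimated correlation or by fry, which tests whether a list moves without comparing it with other genes. Ifng, Foxp3 and Afp were below the count filter.

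The anti-PD1 libraries of batch p103 (n = 3) answered only how high these genes were in that group. The PD-1 gene Pdcd1 was at 1.65 ± 0.761 CPM and its ligand gene Cd274 at 7.81 ± 4.06 CPM. The T cell genes Cd8a and Cd3e were at 2.77 ± 3.86 and 1.54 ± 2.03 CPM, and the granzyme gene Gzmb at 2.73 ± 3.89 CPM, with Cd8a between 0.242 and 7.21 CPM. The ferritin genes Fth1 and Ftl1 were at 1598 ± 253 and 965 ± 60.2 CPM, Tfrc at 86.4 ± 5.43 CPM, Slc40a1 at 11.4 ± 12.4 CPM and Hmox1 at 266 ± 120 CPM. The interferon score was 3.86 ± 0.97 mean log2 CPM and the MHC class II score 4.53 ± 1.24. Group and batch differ together between these libraries and those of p106, so no gene or list was tested between them.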

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

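The tests of liver tissue as a source of hepatocyte transcripts, of leukocyte content and of hepatocyte content were chosen or restated only after the results were seen. So were the alternative with the hepatocyte score as a covariate, that without the most hepatocyte-rich library of each group, and the rule for shares below. The other tests were planned.

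The anti-PD1 libraries, which the comparison does not use, were looked at for shares of 5 lists above those of every vehicle p106 library, by 95% Wilson intervals that do not overlap, and 5 of 15 shares were. Hepatocyte genes took 1.13% of counts in replicate 1 against 0.0232% to 0.554% in the vehicle libraries. Pancreas and gut genes took 3.09% in replicate 2 and 0.256% in replicate 3 against 0.000488% to 0.000741%. B and plasma cell genes took 0.0766% in replicate 2 and 0.0159% in replicate 3 against 0.00133% to 0.00809%. These vehicle libraries are of another batch, and the intervals leave out the spread between mice. No group had 4 or more libraries, so the search for single distant libraries in a group covered 0 measures.

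The first pattern was the spread of hepatocyte transcripts within groups. A candidate explanation is liver tissue beside the tumour in the sampled piece: the mean of 10 genes of other liver cells was higher in the most than in the least hepatocyte-rich library in 3 of 3 groups, by 3.36, 5.31 and 3.91 log2, with 9 of the 10 genes higher in each group. Of these 10 genes, 2 are also in other lists of the set. Tumour cells with hepatocyte features were not tested, and no biological explanation was tested.

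The second pattern was the lower interferon list and higher MHC class II list with ironized anti-PD1. The T cell and macrophage score did not fall with the interferon score: it was higher by 0.544 (SE 0.0957), against -1.11 (SE 0.391). This cannot exclude fewer leukocytes in the treated pieces as a source. The score holds the Kupffer cell gene Clec4f, highest in the most hepatocyte-rich treated library, and T cell genes at low counts, and it leaves out other leukocytes. The interferon list median was -1.11 with the hepatocyte score as a covariate and -1.21 without it. In that linear fit the score accounted for little of the change. A fit of 6 libraries, chosen after the results were seen, cannot exclude hepatocyte content as a cause. As for chance, 10 splits of 6 libraries are too few for a share under 0.05: the real split, 1 of 10, had the largest median for the interferon list (size 1.21, highest other 0.972) and for the MHC class II list, 1 of 10 (1.53, highest other 0.871). Both lists were picked for their small p values in the real split, which favours that split in this ranking. For the MHC class II list the content of leukocytes was not tested. Treatment remains open, and so does any difference between the pieces that went with it.

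The third pattern was the counts of calls, for which 10 splits are again too few for a share under 0.05. At least 21 lists were called by camera in 2 of 10 splits (highest other 26), and the other splits had a median of 16 lists and at least 12. For edgeR the splits test nothing, since a real count of 0 is reached by any split (10 of 10, highest other 0). DESeq2 called at least 50 genes in 5 of 10, with 710 in the highest other split. That split set vehicle replicate 2 and ironized replicates 1 and 2 against the rest, the 3 libraries of p106 with the highest hepatocyte shares (0.554%, 1.18% and 0.192%, next 0.0598%). Other splits also gave more genes than the real one, with 64, 105 and 228. The hepatocyte shares were set beside the highest split after its count was seen. What sets these counts was not tested.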

How the results depend on the processing

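The alternatives with the hepatocyte score as a covariate and without the most hepatocyte-rich library of each group were chosen only after the results were seen. The others were chosen before the data were examined. Where a result changed, the cause was not tested unless a cause is given. The alternatives set for anti-PD1 against vehicle in p103, for the difference of effects, for the vehicle groups and for the correlation of effects were not run for this text, nor was the fit of all 4 groups, because the vehicle p103 libraries were not used here.

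The 0 genes of edgeR (638 at an unadjusted p under 0.05) became 50 with DESeq2 and stayed at 0 in all 6 fits with a library left out. The 21 lists became 0 with an estimated correlation and 0 by fry, and 16 to 25 with 1 library left out. Without ironized replicate 1 the hepatocyte list turned to -0.943 (adjusted p = 0.192) and the complement list to -0.554 (0.358), against highest medians of 3.73 and 2.85 without vehicle replicate 2. Without vehicle replicate 1 the test of the hepatocyte list reversed at a median of 0.507 (0.874). With the covariate, which removes this score by construction, the hepatocyte list was not called (-0.0361, adjusted p = 0.967), nor was the complement list (0.237, 0.565). Without the most hepatocyte-rich library of each group 7 lists were no longer called: classically activated macrophages (-0.394), interferon-gamma (-0.259), chemokines (-0.244, adjusted p = 0.291), NF-kappaB (0.0490), erythroid (0.719), oncofetal liver (0.482, 0.0607) and heat shock (-0.129). The replicate block ended the hepatocyte (-0.117, 0.278), complement (0.206, 0.320), classically activated (-0.535, 0.0604) and NF-kappaB (-0.0532, 0.0850) calls. The strict filter ended the complement (1.003, 0.0944) and cholangiocyte and hepatic progenitor (0.648, 0.124) calls, and no filter the NF-kappaB call (-0.0435, 0.0889).

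Among values under all alternatives, 1216 for single genes kept their direction and side of the threshold, 21 moved and 15 newly passed, all 15 with DESeq2. No gene passed in the main fit, so the 1216 values kept their sign and stayed uncalled. For lists, 240 were unchanged, 89 were no longer called and 3 reversed. No named gene and no median of a called list changed sign under RLE, upper quartile or library size scaling. Replicate numbers gave no sign of pairing: same-number correlations ran from -0.64 to 0.21 and the others from -0.72 to 0.75. With 3 libraries in each group this cannot exclude a pairing. The variance between replicates (9 pairs, Pearson 0.856 to 0.973) was 51.1 to 232 times that of counting error, by chi-square per degree of freedom. This measure is summed over genes and is not that of a typical gene. Its highest value was for anti-PD1 replicates 1 and 2. Whether more reads would change the gene tests was not tested.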

Other observations

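Several lists that were tested and not called bear on the question of the study. With ironized anti-PD1 the median log2 changes were 0.21 for PD-1 and B7 ligands (camera adjusted p = 0.225), 0.35 for T cell checkpoints and exhaustion (0.115), -0.08 for MHC class I (0.220), -0.05 for regulatory T cells (0.824), 0.27 for dendritic cells (0.574), -0.09 for neutrophils (0.866), 0.06 for ribosomal proteins (0.193) and -0.02 for heme metabolism (0.340).

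Ifng was at 0.0138 and 0.0265 CPM with vehicle p106 and ironized anti-PD1, Foxp3 at 0.219 and 0.239 CPM, and Afp, the alpha-fetoprotein gene that many hepatocellular carcinomas express, at 0.243 and 0.492 CPM. None of the 3 genes passed the count filter, so they are given as values without a test. With anti-PD1 in p103 Ifng was at 0.152 ± 0.149 CPM (SD, n = 3), Foxp3 at 0.539 ± 0.538 CPM and Afp at 0.361 ± 0.0948 CPM.

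In the anti-PD1 libraries of p103 (n = 3) the score of T cell genes was -0.23 ± 1.46 mean log2 CPM, of B and plasma cell genes 0.72 ± 1.71, of macrophage genes 5.73 ± 0.47, of cell cycle genes 7.01 ± 0.08 and of fibroblast and collagen genes 8.06 ± 0.31. No vehicle group of p103 was used here to set beside them.

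The mitochondrial share of counts ran from 1.16% to 1.30% in the p103 libraries used and from 0.866% to 2.64% in p106. Annotated pseudogenes took 0.814% to 0.877% of counts in the former and 1.18% to 1.60% in the latter.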
